A study of Mus musculus with 7 samples.

How the data were processed

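The samples were 7 Affymetrix Mouse Gene 1.0 ST arrays of RNA from mouse splenic NK cells cultured for 8 h, 4 with IL2 at 250 U/ml and 3 untreated. The titles of untreated replicate 2 and IL2 replicates 1 and 2 do not give the time, and 8 h was taken for them from the other labels. By the sample labels, the cells came from 6-week-old male C57BL/6 mice and were enriched with an EasySep negative selection kit. RNA was extracted with TriZol, amplified with the Ambion WT Expression kit and labelled with biotin. The intensity values were deposited as 1 value per transcript cluster and array, made with Affymetrix Power Tools and RMA per the submitters' processing notes. The versions of both and the settings of RMA were not given in the sources used here. The titles mark the arrays as re-analysed, and no label says which arrays of the larger series were normalized together. The values were on a linear scale and were brought to log2 with no offset.

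The table held 24922 probes, of which 21425 had 1 gene symbol, 1399 several and 2098 none, and those with exactly 1 symbol were tested. For 21347 of them the Entrez identifier was in the reference table of mouse genes, and 0 symbols needed updating. For the 921 genes with more than 1 probe the brightest probe was kept, which left 19752 genes with no filter on signal. Among the 588 called genes 33 had more than 1 probe, and 0 of these had a probe of the opposite sign. On 53.3% of the probes at least 2 arrays held exactly equal values, and on 37.9% 2 arrays of 1 group did, which lowers the measured spread. This was so for 0.51% of the called genes. The moderated fit draws on the spread of all genes, so that equal values elsewhere may also affect the SE of called genes.

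Groups were taken from the sample labels. The log2 values of the 7 arrays were fitted in limma 3.58.1 under R 4.3.3 with 1 factor, IL2 or untreated, and eBayes with its default settings (7.68 degrees of freedom in total). Benjamini-Hochberg correction over all genes gave the adjusted p, with a threshold of 0.05. A fold change of at least 2 was counted as well. Fold changes are means over arrays, the SE is that of limma's moderated fit, and ± gives the SD over arrays. Arrays of the 2 groups were called apart when every IL2 array lay above, or every one below, every untreated array.

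The 41 gene lists (19 on NK cell and IL2 biology, 12 used in the closing section and 10 of cell type markers) were written from general knowledge. So were the design, the test, the rule for naming genes and the alternative settings, all before the data were examined. Each list with at least 5 members measured was tested with camera (preset correlation of 0.01 between genes, Benjamini-Hochberg over lists). It was tested again with a correlation estimated from the data, and with fry. Members were also counted with the correction taken over the list alone. Named genes were the 8 largest rises and the 8 largest falls among called genes with the groups apart. To these were added the 2 called members with the largest change of each list (the 1 with the largest change where none was called) and a set of genes always named. Other genes are marked in the text as named after their values were seen. Some list members were not analysed here.

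These settings were the replicate number as a block, the style of the sample titles as a block, and only genes at or above the median signal. Others were quantile normalization again, centring each array on its median, eBayes with trend and robust, array quality weights (with statmod 1.5.0), the mean of all probes of a gene, all probes, and leaving out each array in turn. Fits over the 4 arrays whose titles give the time and over the 3 whose titles do not were added after the data had been seen. In the latter the single untreated array was taken to vary like the IL2 arrays. The fit was tested on simulated data with the same group sizes, in which 100 genes changed by 1 and 100 by 2 on the log2 scale. It recovered 73% and 100% of them, and 6.49% of its calls were genes that had not been changed. The simulated noise was normal and independent between genes, with no effect of title style and no equal values. These shares thus need not hold for the real arrays. No sample and no column of values was left out.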

Results

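Gene expression was measured in cells enriched for natural killer (NK) cells, innate lymphocytes that kill infected or transformed cells, from the spleens of 6-week-old male C57BL/6 mice. Markers of B cells and myeloid cells were also bright in the untreated arrays, so that the changes below cannot be assigned to NK cells from these values alone. The cells had been enriched by negative selection, in which other cell types are labelled and removed, and were cultured for 8 h with interleukin 2 (IL2, 250 U/ml) or without cytokine. The series held 4 IL2 arrays (replicates 1 to 4) and 3 untreated arrays (replicates 2 to 4), each an Affymetrix Mouse Gene 1.0 ST array of 1 RNA sample. The question set by the series title was how NK cells respond to IL2 in vitro. The median intensity per array ranged from 121 in IL2 replicate 2 to 131 in untreated replicate 4, and the 75th percentile from 278 in untreated replicate 3 to 350 in IL2 replicate 4. Across all probes, which are not independent replicates, Pearson's r of the log2 values was 0.981 to 0.985 within the untreated arrays, 0.979 to 0.995 within the IL2 arrays and 0.966 to 0.985 between the groups. The first principal component (49.5% of the variance) placed every untreated array below 0 and every IL2 array above 0. The second (23.2%) placed untreated replicate 4 and IL2 replicates 3 and 4 on one side and the other arrays on the other side. No label says whether the replicates came from separate mice or cultures, so that the p-values measure only the spread between these samples.

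After 8 h with IL2, 10 of 23 cytotoxic genes, 7 of 19 cytokine and chemokine genes, 27 of 31 interferon-stimulated genes and 20 of 45 MYC and ribosome biogenesis genes were higher than in untreated cells. Camera called these 4 lists, but 0 of them with an estimated correlation (adjusted p of 0.163 to 0.176). Leaving out 1 array took these counts as low as 5 (without untreated replicate 3 or 4 or IL2 replicate 2 or 3), 4 (without IL2 replicate 2), 9 (without untreated replicate 4) and 4 (without IL2 replicate 2 or 3). Over the same arrays 7 of 17 macrophage and monocyte markers were lower (median -0.95). Granzyme B, a serine protease of cytotoxic granules, rose 33.7-fold, and interferon-gamma, the signature cytokine of NK cells, rose 11.1-fold. The largest falls were in the adhesion receptor gene Adgre4 and the proteoglycan gene Vcan. Of 19752 genes tested with limma, 410 were higher and 178 lower with IL2 at a Benjamini-Hochberg adjusted p under 0.05, of which 222 and 82 changed at least 2-fold. For all 588 called genes, the IL2 arrays lay entirely on one side of the untreated arrays, as they did for 9.63% of all genes against 5.71% by chance. With so few arrays this separation largely follows from passing the test and is no separate support for the calls. When the arrays were quantile normalized again, 694 genes were higher and 577 lower, so that the share of higher calls went from 69.7% to 54.6%. With the style of the sample titles (replicates 3 and 4 name the time, replicates 1 and 2 do not) as a block, 579 genes were higher and 247 lower. Over the 4 arrays that name the time, 81 genes were higher and 22 lower. Over the other 3 arrays, of which 1 was untreated, limma called 0 genes either way, with 2630 at an unadjusted p under 0.05. The count of higher genes was 178 without untreated replicate 3, 162 without untreated replicate 4, and 134, 144 and 159 without IL2 replicates 2, 3 and 4. For those at least 2-fold higher it was 133, 131, 117, 127 and 131 in the same order. The count of lower genes was 79 without untreated replicate 4 and 65, 90 and 104 without IL2 replicates 2, 3 and 4, and that of genes at least 2-fold lower was 51 without IL2 replicate 2.

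**Figure D1:**
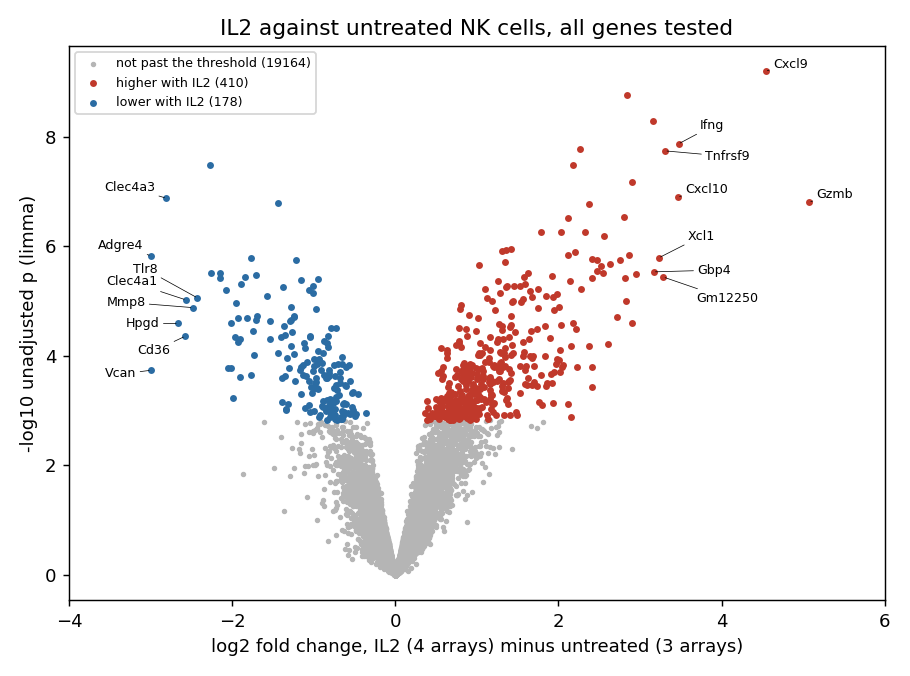
Each point is 1 of the 19752 genes, with the log2 fold change (IL2 minus untreated) on the horizontal axis and the negative log10 of limma's unadjusted p on the vertical axis. Red points are the 410 genes higher and blue points the 178 genes lower at an adjusted p under 0.05, and the named points are the 8 largest rises, led by Gzmb at 5.07, and the 8 largest falls, led by Adgre4 at -3.00.

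The largest rise of all called genes was in granzyme B. Gzmb (transcript cluster 10420308) went from a log2 intensity of 7.90 ± 0.70 (SD, n = 3) in untreated cells to 12.97 ± 0.08 (n = 4) with IL2, a log2 fold change of 5.07 (SE 0.28, limma adjusted p = 0.000234). Cxcl9 and Cxcl10, which encode ligands of the chemokine receptor CXCR3 and are induced by interferons, rose by 4.54 (SE 0.12, limma adjusted p = 1.26e-05) and 3.46 (SE 0.19). Ifng rose from 7.22 ± 0.11 to 10.69 ± 0.25, a log2 fold change of 3.47 (SE 0.14, limma adjusted p = 5.98e-05). Tnfrsf9, the co-stimulatory receptor 4-1BB, rose by 3.31 (SE 0.14), and Xcl1, a chemokine that attracts cross-presenting dendritic cells, rose by 3.23 (SE 0.25). The interferon-inducible GTPase genes Gm12250 and Gbp4 rose by 3.29 (SE 0.28) and 3.17 (SE 0.26). All 8 of these calls held with each of the 7 arrays left out in turn.

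The 8 largest falls were in Adgre4 (-3.00, SE 0.23, limma adjusted p = 0.00109), Vcan (-3.00, SE 0.45), Clec4a3 (-2.81, SE 0.15), Hpgd (-2.67, SE 0.30), Cd36 (-2.58, SE 0.31), Clec4a1 (-2.57, SE 0.25), Mmp8 (-2.49, SE 0.25) and Tlr8 (-2.43, SE 0.23). Clec4a1 and Clec4a3 encode C-type lectin receptors of myeloid cells, Cd36 a scavenger receptor, Mmp8 the neutrophil collagenase and Tlr8 an endosomal Toll-like receptor. Lyz2, the lysozyme gene of myeloid cells, fell from 12.66 ± 0.11 to 10.89 ± 0.23, by 1.77 on the log2 scale (SE 0.14, limma adjusted p = 0.00109). Of 17 measured markers of macrophages and monocytes, 7 fell and 0 rose, with a median log2 fold change of -0.95. The call of Vcan ended without untreated replicate 3, untreated replicate 4 or IL2 replicate 2, at limma adjusted p-values of 0.0573 to 0.0909. Cross-hybridisation between members of the Clec4a family, as of other multigene families named here, cannot be ruled out from these values.

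Of the IL2 receptor chains measured, the alpha and beta chain genes rose, as did 11 of 16 STAT5 target genes. Il2ra, the high-affinity receptor chain, rose from 8.36 ± 0.15 (n = 3) to 10.37 ± 0.39 (n = 4), by 2.01 (SE 0.20, limma adjusted p = 0.00282), and Il2rb, the chain shared with the interleukin 15 receptor, by 1.47 (SE 0.17). Of 9 measured members of the IL-2 receptor and JAK-STAT5 list, these genes and Il15ra (0.91, named after its value was seen) rose, 0 fell and 6 did not pass the test (5 higher when adjusted over the list alone). Of 16 STAT5 target and feedback genes, 11 rose and 0 fell (14 higher when adjusted over the list alone). Among them were the cytokine signalling inhibitors Socs1 (2.84, SE 0.09, limma adjusted p = 1.73e-05), Cish (1.94, SE 0.19) and Socs2 (0.78, SE 0.16), the cyclin gene Ccnd2 (2.56, SE 0.17) and the survival gene Bcl2 (2.21, SE 0.16). The medians were 0.55 for the receptor list (camera adjusted p = 0.000659, but adjusted p = 0.242 with an estimated correlation) and 0.98 for the STAT5 targets (camera adjusted p = 3.23e-22, but adjusted p = 0.163 with an estimated correlation). Arrays whose titles give the time had medians of 0.75 and 1.20, and those whose titles do not had 0.09 and 0.90, beside -0.76 and -1.40 for the macrophage and monocyte markers. The camera call of the receptor list ended over the arrays without the time (adjusted p = 0.664), and its median was 0.32 without untreated replicate 3. The count of STAT5 targets higher was 7 without untreated replicate 3 or IL2 replicate 2, and Socs2 lost its call without any 1 array other than IL2 replicate 1, at limma adjusted p-values of 0.062 to 0.184.

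**Figure D2:**
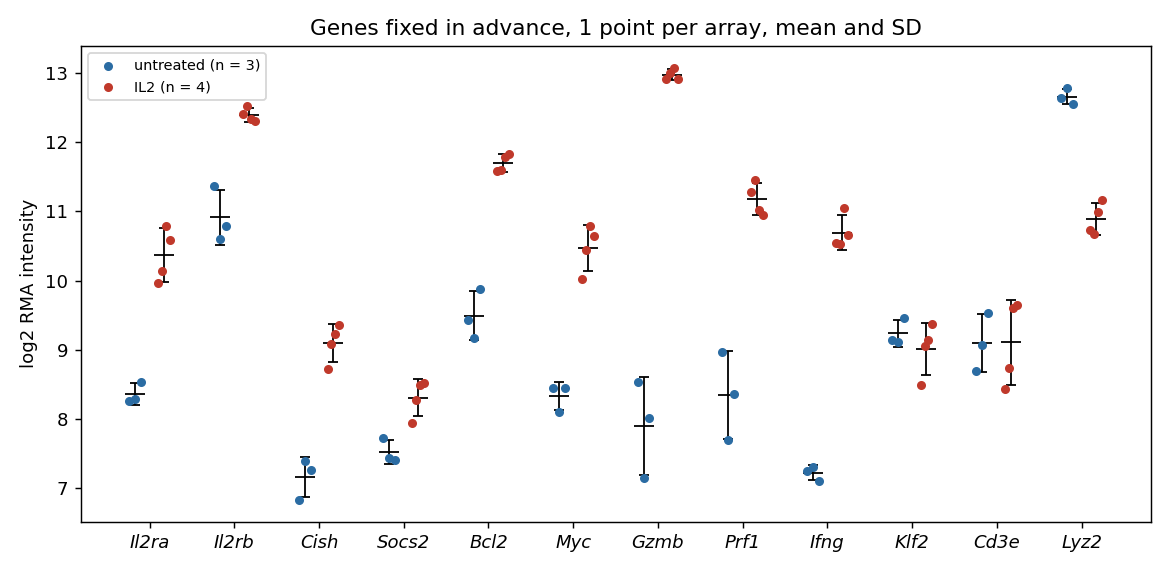
Log2 RMA intensity (vertical axis) of 12 genes named before the data were examined, with 1 point per array, untreated in blue (n = 3) and IL2 in red (n = 4), and black marks for the mean and SD. The 4 IL2 arrays lie above all 3 untreated arrays for Il2ra, Il2rb, Cish, Socs2, Bcl2, Myc, Gzmb, Prf1 and Ifng, overlap with them for Klf2 and Cd3e, and lie below them for Lyz2.

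Effector genes rose in part of each list. Of 23 cytotoxic granule and death ligand genes, 10 rose, and 1, Gzmk, fell (-0.80, named after its value was seen). Prf1, the pore-forming protein perforin, rose from 8.34 ± 0.63 to 11.17 ± 0.23, by 2.83 (SE 0.28, limma adjusted p = 0.00238), and Nkg7, a granule membrane protein, by 2.27 (SE 0.09). Of 19 cytokine and chemokine genes, 7 rose and 0 fell, led by Ifng and Xcl1, while Il2, Il4, Il5, Il10 and Il13 (named after their values were seen) had log2 fold changes between -0.11 and 0.08 that did not pass the test. Adjusted over the list alone, 14 cytotoxic genes were higher and 2 lower, and 9 cytokine genes were higher. The list medians were 0.66 for the cytotoxic genes (camera adjusted p = 1.96e-09, but adjusted p = 0.163 with an estimated correlation) and 0.25 for the cytokines (camera adjusted p = 2.41e-08, but adjusted p = 0.163 with an estimated correlation). In the title styles with and without the time they were 0.71 and 0.25 for the cytotoxic genes and 0.42 and 0.13 for the cytokines, while the macrophage and monocyte markers had a median of -0.95 over all arrays. Among genes at or above the median signal the medians were 1.19 over 17 cytotoxic and 1.15 over 11 cytokine genes. Without untreated replicate 3 or 4 or IL2 replicate 2 or 3 the count of cytotoxic genes higher was 5, and without IL2 replicate 4 it was 6. Gzmk lost its call without each of these 5 arrays. The count of cytokine genes higher was 4 without IL2 replicate 2, and the median of the list was 0.12 without untreated replicate 3 and 0.42 without untreated replicate 2 or 4.

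Some NK receptor, co-receptor and transcription factor genes rose. Of 25 activating and inhibitory NK receptor genes, 10 rose and 0 fell. The largest rises among them were in Klrb1a, of the NKR-P1 lectin family, at 2.48 (SE 0.20), and Ncr1, the activating receptor NKp46, which went from 9.28 ± 0.17 to 11.46 ± 0.07, by 2.18 (SE 0.10, limma adjusted p = 8.22e-05). Of 19 activation-induced co-receptor genes, 5 rose, namely Tnfrsf9, Cd69 (1.65, SE 0.15), Tnfrsf18, Icos and Nr4a3 (the last 3 named after their values were seen). None of the 19 fell. Of 20 transcription factors of NK maturation, 7 rose, led by Tbx21 (1.42, SE 0.16), which encodes T-bet, and Nfil3 (1.38, SE 0.23), and 1, Zeb2, fell (-0.68, named after its value was seen). Adjusted over the list alone, 16 receptors, 7 co-receptors and 9 transcription factors were higher, and 1 of each was lower. The medians were 0.78 (camera adjusted p = 4.11e-13, but adjusted p = 0.225 with an estimated correlation), 0.24 (camera adjusted p = 1.64e-06, but adjusted p = 0.242 with an estimated correlation) and 0.17 (camera adjusted p = 8.67e-06, but adjusted p = 0.242 with an estimated correlation). By title style, with and without the time, they were 0.76 and 0.55, 0.49 and 0.16, and 0.42 and 0.07, beside the median of -0.95 for macrophage and monocyte markers over all arrays. The camera calls of the last 2 lists ended over the arrays without the time, at adjusted p-values of 0.0994 and 0.174. The count of receptors higher was 4 without untreated replicate 4 and 6 without IL2 replicate 3. The count of co-receptors was 3 without untreated replicate 3 or IL2 replicate 2, 3 or 4. The count of transcription factors was 3 without untreated replicate 3 or IL2 replicate 3 or 4, 2 without IL2 replicate 2 and 4 without untreated replicate 4. Zeb2 lost its call without any untreated array or IL2 replicate 2 or 4. The medians were 0.50 for the receptors without untreated replicate 4, 0.37 for the co-receptors without IL2 replicate 2 and 0.27 for the transcription factors without IL2 replicate 1. They were 0.61 for 14 co-receptors at or above the median signal, and 0.27 and 0.26 for the transcription factors with the replicate number as a block and with array quality weights. Nfil3 lost its call without untreated replicate 2 or 3 or IL2 replicate 2, 3 or 4, at limma adjusted p-values of 0.0512 to 0.0958.

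The MYC and ribosome biogenesis list, which holds nucleolar assembly factors and known MYC targets, had no member with a fall. Of its 45 measured members, 20 rose and 0 fell, all 45 had a positive log2 fold change, and 40 were higher when adjusted over the list alone. Myc itself rose from 8.33 ± 0.20 (n = 3) to 10.47 ± 0.33 (n = 4), by 2.14 (SE 0.19, limma adjusted p = 0.00153), and Srm, the spermidine synthase gene, by 1.90 (SE 0.23). The list's median was 0.87 (camera adjusted p = 1.79e-34, but adjusted p = 0.176 with an estimated correlation), and it was 1.10 within the title style with the time and 0.57 without it. The count of members higher was 31 after quantile normalization again and with the replicate number as a block, 13 without untreated replicate 2, 5 without untreated replicate 3 or 4 or IL2 replicate 4, and 4 without IL2 replicate 2 or 3. Macrophage and monocyte markers (median -0.95) and NK cell identity markers (median 1.05) moved over the same arrays. The median of the MYC list stayed between 0.76 and 1.00 with each array left out in turn.

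Few metabolic genes were called. Of 27 amino acid transport and ATF4-linked biosynthesis genes, 6 rose, led by Slc7a5 (1.68, SE 0.27), a transporter of large neutral amino acids, and 1 fell, the cystine transporter gene Slc7a11 (-1.90, SE 0.23), with 10 higher and 1 lower when adjusted over the list alone. Of 15 glycolysis genes, Pfkp, a phosphofructokinase gene, rose (1.28, SE 0.17), Slc16a3, a lactate transporter gene, fell (-0.90, SE 0.17) and 13 did not pass the test, with 4 higher and 1 lower when adjusted over the list alone. Of 20 cholesterol biosynthesis and uptake genes, 0 were called either way by limma over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05. The largest difference was 0.74 (SE 0.20, limma adjusted p = 0.114) for Lss, the lanosterol synthase gene, which passed the test after quantile normalization again (0.72, limma adjusted p = 0.0424). The medians were 0.44 for the amino acid list (camera adjusted p = 8.67e-06, but adjusted p = 0.242 with an estimated correlation), 0.35 for glycolysis (camera adjusted p = 0.0124, but adjusted p = 0.581 with an estimated correlation) and 0.12 for cholesterol (camera adjusted p = 0.0242, but adjusted p = 0.566 with an estimated correlation). Within the title styles with and without the time they were 0.72 and 0.28, 0.54 and 0.07, and 0.22 and -0.01, so that the cholesterol list did not keep its direction within the second style. Macrophage and monocyte markers, with a median of -0.95, fell across the same arrays. The count of glycolysis genes higher was 2 with title style or replicate number as a block, among genes at or above the median signal and with centred arrays, and 3 after quantile normalization again and with array quality weights. The count of amino acid genes higher was 10 with title style or replicate number as a block, 1 without untreated replicate 2 or 3 or IL2 replicate 4, 2 without untreated replicate 4, and 0 without IL2 replicate 2 or 3. The glycolysis call of camera ended without untreated replicate 3 (adjusted p = 0.0544), without IL2 replicate 4 (0.0672), after quantile normalization again (0.0534), among genes at or above the median signal (0.125) and over the arrays without the time (0.757). The cholesterol call ended without untreated replicate 3 (0.076), IL2 replicate 2 (0.0555) or IL2 replicate 4 (0.0884), after quantile normalization again (0.395) and among genes at or above the median signal (0.258). The glycolysis median was 0.11 without untreated replicate 3 and 0.21 without IL2 replicate 4, and the cholesterol median 0.04 and 0.05 without these arrays and 0.20 without IL2 replicate 1. After quantile normalization again the medians were 0.20 and 0.00, and the cholesterol median was 0.20 with the replicate number as a block and 0.18 with array quality weights. Slc7a5 lost its call without untreated replicate 2 or 3 or IL2 replicate 2, 3 or 4 (limma adjusted p-values of 0.0712 to 0.0954). Slc16a3 lost it without any 1 array other than IL2 replicate 4 (0.0624 to 0.148) and with array quality weights (0.0671).

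Few cell cycle genes passed the test. Of 38 G1-S and DNA replication genes, 3 rose, namely the cyclin gene Ccnd2 (2.56), its kinase partner Cdk6 (1.43, SE 0.14, limma adjusted p = 0.00244) and Pcna (0.39, named after its value was seen), and 0 fell, with 6 higher when adjusted over the list alone. Of 28 G2-M genes, limma called 0 either way, also when adjusted over the list alone or at an unadjusted p under 0.05. Mki67, the proliferation marker Ki-67, differed by -0.40 (SE 0.34, limma adjusted p = 0.716). Of 30 quiescence and FOXO target genes, 4 fell and 0 rose, with 6 lower when adjusted over the list alone. They were the interleukin 7 receptor gene Il7r (-1.71, SE 0.19), the lymphocyte egress receptor gene S1pr1 (-0.87, SE 0.11), and Ypel3 and Fbxo32, which were named after their values were seen. Klf2, a transcription factor of quiescent lymphocytes, differed by -0.23 (SE 0.20, limma adjusted p = 0.733). The medians were 0.29 for G1-S (camera adjusted p = 2.01e-08, but adjusted p = 0.258 with an estimated correlation), -0.21 for G2-M (camera adjusted p = 0.0227, but adjusted p = 0.68 with an estimated correlation) and -0.27 for quiescence (camera adjusted p = 2.11e-06, but adjusted p = 0.258 with an estimated correlation). Within the title styles with and without the time they were 0.41 and 0.10, -0.11 and 0.06, and -0.14 and -0.40, so that the G2-M median did not keep its sign within the second style. The G2-M call of camera also ended with title style as a block (adjusted p = 0.0581), with the replicate number as a block (0.112) and without untreated replicate 3 (0.145), untreated replicate 4 (0.457), IL2 replicate 1 (0.265) or IL2 replicate 2 (0.0922). The G2-M median was -0.41 without untreated replicate 2, -0.01 without untreated replicate 4, -0.10 without IL2 replicate 1 and -0.13 without IL2 replicate 2, and the quiescence median -0.14 without untreated replicate 4. With title style or replicate number as a block the G2-M median was -0.12 or -0.10, and with array quality weights the quiescence median was -0.18. The count of quiescence genes lower was 10 after quantile normalization again and 2 without untreated replicate 4 or IL2 replicate 2, 3 or 4. The count of G1-S genes higher was 2 without untreated replicate 3 or 4 or IL2 replicate 2, 3 or 4, and 5 without IL2 replicate 1. It was 6 with the replicate number as a block and among genes at or above the median signal, and 5 with array quality weights. Macrophage and monocyte markers had a median of -0.95 beside these lists.

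Survival and homing genes changed one by one rather than as lists. Of 13 genes of the BCL2 family, Bcl2 rose from 9.49 ± 0.35 to 11.70 ± 0.13, by 2.21 (SE 0.16, limma adjusted p = 0.00105), Bcl2l1, which encodes the anti-apoptotic protein BCL-XL, rose by 1.04 (SE 0.14), and the pro-apoptotic gene Bmf fell (-0.63, named after its value was seen). The list's median (-0.02) and mean (0.25) differed in sign, and camera, which gave an upward direction, did not call it (adjusted p = 0.458). Of 21 migration and homing receptor genes, 2 rose, Cd69 and the integrin gene Itga2 (1.10), and 3 fell, the fractalkine receptor gene Cx3cr1 (-1.35, SE 0.16), Cxcr4 (-0.97) and S1pr1 (-0.87), of which Itga2 and Cxcr4 were named after their values were seen. Their median was -0.05 (camera adjusted p = 0.141), and camera called the list lower after quantile normalization again (adjusted p = 0.024), over the arrays without the time (0.000554, where the untreated group is 1 array) and without untreated replicate 3 (0.0229). That median was -0.01 without untreated replicate 2, -0.10 without untreated replicate 3, -0.08 without IL2 replicate 2, -0.07 without IL2 replicate 4 and -0.14 after quantile normalization again. With centred arrays the homing median was -0.02 and the BCL2 family median 0.01. Adjusted over the list alone, 2 genes were higher and 1 lower in the BCL2 family, and 2 higher and 4 lower among the homing receptors. Separated by title style, with and without the time, the medians were -0.02 and -0.03 for the BCL2 family and 0.00 and -0.19 for the homing receptors, beside macrophage and monocyte markers at -0.76 and -1.40. Bcl2l1 lost its call without untreated replicate 3 or 4 or IL2 replicate 2 (limma adjusted p-values of 0.0501 to 0.0634), and Bmf without any 1 array other than IL2 replicate 1. With the replicate number as a block, 4 genes of the BCL2 family were higher and 0 lower. Without IL2 replicate 2, 3 or 4 the count of homing receptors higher was 1.

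Most interferon-stimulated genes rose. Of 31 measured members, 27 rose and 0 fell, all 31 had a positive log2 fold change, and all 31 were higher when adjusted over the list alone. Zbp1, a sensor of Z-form nucleic acids, rose from 8.17 ± 0.47 (n = 3) to 11.13 ± 0.32 (n = 4), by 2.96 (SE 0.25, limma adjusted p = 0.00145), and Usp18, a negative regulator of interferon signalling, by 2.90 (SE 0.33). The median was 1.80 (camera adjusted p = 4.73e-39, but adjusted p = 0.163 with an estimated correlation), with 2.36 within the title style with the time and 1.09 without it. Over the same arrays macrophage and monocyte markers had a median of -0.95 and NK cell identity markers one of 1.05. The count of members higher was 11 without untreated replicate 3, 9 without untreated replicate 4, and 13, 15 and 12 without IL2 replicates 2, 3 and 4, while the median stayed between 1.57 and 1.98 and all 31 members stayed positive.

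By contrast, camera did not call the NF-kB list or the immediate early and dissociation stress list. Of 18 NF-kB target and regulator genes, only Nfkbiz, an atypical inhibitor protein gene, rose (0.71, SE 0.15, limma adjusted p = 0.0489) and 0 fell, as was also the case when adjusted over the list alone. Of 21 immediate early and stress genes, 3 rose, the transcription factor genes Jun (1.30, SE 0.15) and Egr1 (0.97, SE 0.16) and the chaperone gene Hsp90aa1 (0.61, named after its value was seen), and 0 fell, with 5 higher and 2 lower when adjusted over the list alone. The medians were 0.09 (camera adjusted p = 0.0837) and 0.04 (camera adjusted p = 0.0678), and within the title styles with and without the time 0.27 and -0.08, and 0.33 and -0.07. Camera called both lists higher over the arrays that name the time (adjusted p = 0.00136 and 0.00632), with the replicate number as a block (0.00965 and 0.027) and without IL2 replicate 1 (0.00968 and 0.00761). The last 2 settings share their fold changes, since IL2 replicate 1 does not enter the contrast in either. The NF-kB list was also called without untreated replicate 2 (0.0168) and with array quality weights (0.0146). Nfkbiz lost its call without untreated replicate 3 or 4 or IL2 replicate 2, 3 or 4 (limma adjusted p-values of 0.143 to 0.188), with title style (0.0552) or replicate number (0.0583) as a block and with a trended, robust variance (0.0563). The NF-kB count was 2 without untreated replicate 2. The medians were 0.17 and 0.20 with the replicate number as a block, 0.15 and 0.12 with array quality weights, and 0.01 and 0.04 after quantile normalization again. The NF-kB median was 0.03 without untreated replicate 3 or IL2 replicate 3, 0.05 without IL2 replicate 4 and 0.17 without IL2 replicate 1. The immediate early median was -0.01 without untreated replicate 3 or IL2 replicate 3 or 4, 0.03 without untreated replicate 2, 0.08 without IL2 replicate 2, 0.12 without untreated replicate 4 and 0.20 without IL2 replicate 1. The immediate early count was 5 (and 1 lower) with title style as a block, 4 (and 1 lower) with the replicate number as a block, 2 without untreated replicate 2 or 3 or IL2 replicate 2, and 1 without untreated replicate 4 or IL2 replicate 3 or 4. Egr1 lost its call without any 1 array other than IL2 replicates 1 and 2 (limma adjusted p-values of 0.0655 to 0.105). Macrophage and monocyte markers had a median of -0.95 over the same arrays.

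**Figure D3:**
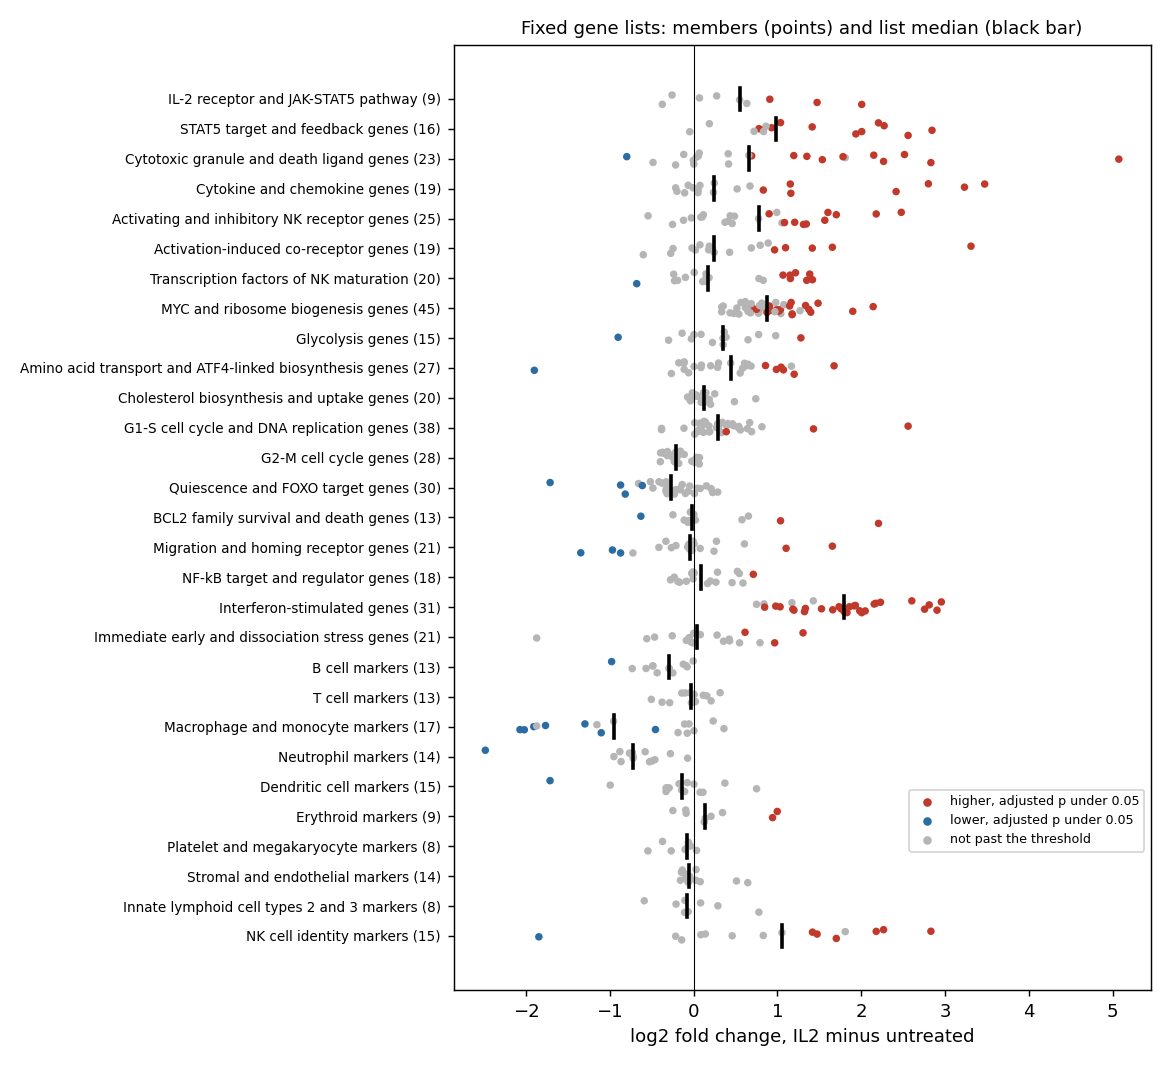
Log2 fold change (IL2 minus untreated, horizontal axis) of every measured member (points) of the 19 main lists and the 10 lists of cell type markers, with the number measured in brackets and the list median as a black bar. Red and blue points are members higher and lower at an adjusted p under 0.05. The 31 interferon-stimulated genes and the 45 MYC and ribosome biogenesis genes all lie right of 0, and 7 macrophage and monocyte markers are blue.

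Markers of the enriched cell type and of the cell types that negative selection removes were followed in the same arrays. Of 15 NK cell identity markers, 6 rose, including Prf1, Nkg7 and Ncr1, and 1, Cd7, fell (-1.85, named after its value was seen), with a median of 1.05 (camera adjusted p = 2.31e-08, but adjusted p = 0.236 with an estimated correlation). All but Cd7, Fcer1g and Tyrobp also belong to the NK receptor, transcription factor, cytokine, cytotoxic or IL-2 receptor lists. The rise of the identity markers is thus not independent of those lists and does not measure the share of NK cells. Of 17 macrophage and monocyte markers, 7 fell, led by the macrophage adhesion receptor gene Adgre1 (-2.07, SE 0.19, limma adjusted p = 0.00181) and Cd14 (-2.02, SE 0.30), and 0 rose, with a median of -0.95 (camera adjusted p = 1.11e-08, but adjusted p = 0.163 with an estimated correlation). Of 14 neutrophil markers, all had a negative log2 fold change and 1, Mmp8, fell, with a median of -0.72 (camera adjusted p = 8.76e-07, but adjusted p = 0.163 with an estimated correlation). Among 13 B cell markers, Fcer2a, the low-affinity IgE receptor gene, fell (-0.98, SE 0.15), with a median of -0.29 (camera adjusted p = 5.64e-06, but adjusted p = 0.242 with an estimated correlation). Among 15 dendritic cell markers, Cd209a, a C-type lectin gene also known as DC-SIGN, fell (-1.71, SE 0.14), with a median of -0.14 (camera adjusted p = 0.0266, but adjusted p = 0.242 with an estimated correlation). The T cell gene Cd3e had 9.10 ± 0.42 in untreated and 9.10 ± 0.61 in IL2 arrays (difference 0.01, SE 0.34), and of 13 T cell markers limma called 0, also at an unadjusted p under 0.05, with a median of -0.03 (camera adjusted p = 0.671) and the largest difference in Cd5 (-0.51, SE 0.29). Of 9 erythroid markers, Car1 (1.00, SE 0.16) and Tfrc (0.94, SE 0.19), the transferrin receptor gene that dividing cells also express, rose, with a median of 0.14 (camera adjusted p = 0.0454, but adjusted p = 0.432 with an estimated correlation). Limma called 0 platelet, stromal and innate lymphoid type 2 and 3 markers, with 2 of each at an unadjusted p under 0.05.

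The medians of those last 3 marker lists were -0.08 (camera adjusted p = 0.0454, but adjusted p = 0.242 with an estimated correlation), -0.06 (camera adjusted p = 0.817) and -0.08 (camera adjusted p = 0.745). Their largest single differences were -0.55 (SE 0.23) for Ppbp, 0.65 (SE 0.24) for Kdr and 0.78 (SE 0.22) for Gata3, of which Gata3 passed the test after quantile normalization again (limma adjusted p = 0.0408). The means of the stromal list (0.03) and the innate lymphoid list (0.01) had the opposite sign to their medians and to camera's direction. Adjusted over the list alone, 9 NK identity markers were higher and 1 lower, and 10 macrophage and monocyte markers were lower and 1 higher. In the same way, 2 neutrophil and 5 B cell markers were lower, 2 dendritic cell markers were lower and 1 higher, and 2 erythroid markers were higher. Within the title styles with and without the time, the medians were 1.21 and 0.55 for NK identity, -0.76 and -1.40 for macrophages and monocytes, and -0.49 and -0.93 for neutrophils. They were -0.20 and -0.52 for B cells, -0.11 and -0.13 for dendritic cells, 0.17 and -0.10 for T cells, and 0.22 and 0.18 for erythroid cells. The count of macrophage and monocyte markers lower was 3 without untreated replicate 4 or IL2 replicate 2 or 3. With title style as a block, 5 neutrophil markers were lower, and 4 with the replicate number as a block. After quantile normalization again 3 neutrophil, 4 B cell and 2 dendritic cell markers were lower, and 1 macrophage and monocyte marker was higher. Among genes at or above the median signal 2 B cell markers were lower, and the medians were -1.53 for 10 macrophage and monocyte markers, -0.23 for 12 dendritic cell markers and 0.94 for 3 erythroid markers. The closing section uses a different cut, with signal judged by the untreated mean. That cut kept 11 macrophage and monocyte markers (median -1.30) and 11 dendritic cell markers (median -0.29). Single-array dependence also touched Cd14, whose call ended without untreated replicate 4 or IL2 replicate 2 or 3 (limma adjusted p-values of 0.0572 to 0.0852), and Fcer2a, without untreated replicate 2, 3 or 4 or IL2 replicate 2 or 3 (0.0576 to 0.0891). Car1 lost its call without untreated replicate 2 or 4 or IL2 replicate 2, 3 or 4 (0.0554 to 0.094), and Tfrc without any 1 array other than IL2 replicate 1 (0.0858 to 0.164), so that 0 erythroid markers were called without untreated replicate 2 or 4 or IL2 replicate 2, 3 or 4, and 1 without untreated replicate 3. The camera call of the dendritic cell list ended without untreated replicate 2 (0.197) or IL2 replicate 1 (0.0678), over the arrays with the time (0.215), with the replicate number as a block (0.0562) and with array quality weights (0.0722). That of the erythroid list ended without untreated replicate 2 (0.398), untreated replicate 4 (0.0982) or IL2 replicate 3 (0.0633) or 4 (0.0539), over the arrays with the time (0.194) and with array quality weights (0.119). That of the platelet list ended without untreated replicate 2 (0.0737), untreated replicate 3 (0.0684), IL2 replicate 1 (0.149) or IL2 replicate 4 (0.0579), over the arrays with the time (0.186), with the replicate number as a block (0.0962), with array quality weights (0.086) and with a trended, robust variance (0.0562). The B cell median was -0.19 without untreated replicate 2, and the platelet median -0.13 without untreated replicate 2 or 3 and -0.05 without untreated replicate 4.

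**Figure D4:**
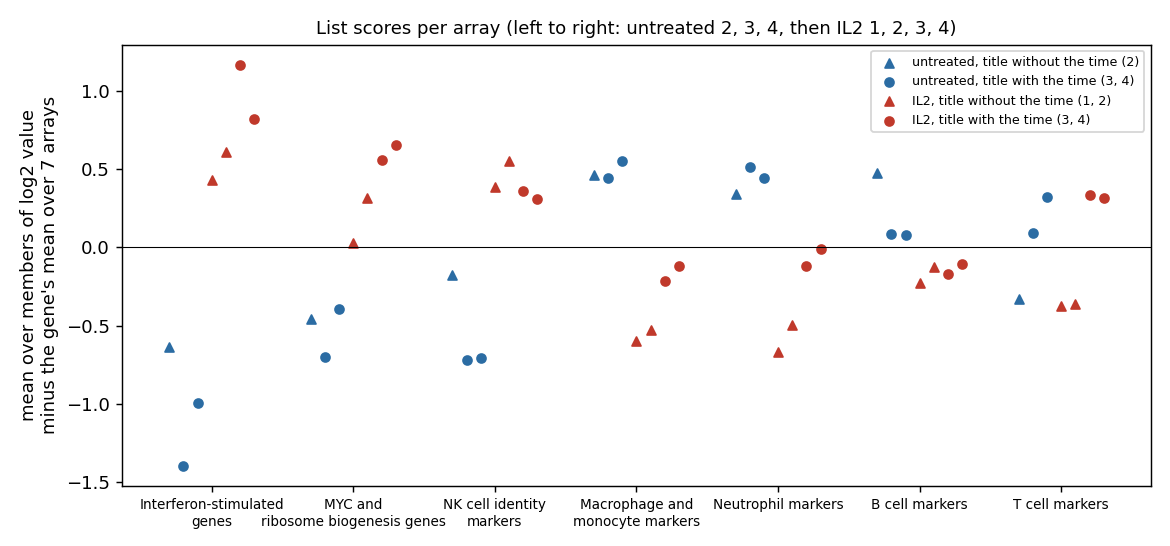
Score of 7 gene lists (vertical axis, mean over the list's members of the log2 value minus the gene's mean over the 7 arrays) in each array, untreated in blue and IL2 in red, with triangles for arrays whose titles lack the time and circles for those that give it. Interferon-stimulated, MYC and ribosome biogenesis, and NK identity scores are higher in all 4 IL2 arrays than in all 3 untreated arrays, and macrophage and monocyte, neutrophil and B cell scores are lower in all 4. T cell scores separate by title style, at -0.38 to -0.33 without the time and 0.09 to 0.33 with it.

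With the preset correlation of 0.01 between genes, camera called 31 of the 41 fixed lists. Of the 41 lists, called or not, 12 are described among the closing observations. With a correlation estimated from the data it called 0 lists, where the lowest adjusted p was 0.163 and 9 lists had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way on balance without comparing them with other genes, 20 lists were called.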

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

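The tests of dilution by NK cell RNA, of scaling, of the choice of bright genes, of the splits by title style, of RNA from other cell types and of the kind of interferon were chosen after the result had been seen, and the other tests of this part were not.

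In 4 of 117 results tested (76 named genes and 41 list scores), 1 of the 4 IL2 arrays lay far from the other 3, against about 1 in 20 by chance. The gap divided by the whole range was 0.879 for Tbx21, 0.864 for Hspa5, 0.849 for Bhlhe40 and 0.844 for the score of the cytotoxic list, each above Dixon's 95% critical value for 4 samples. The array was IL2 replicate 1 each time, below the others: 9.96 against 10.27 to 10.31 for Tbx21, 10.94 against 11.40 to 11.47 for Hspa5, and 8.70 against 9.19 to 9.28 for Bhlhe40. The cytotoxic score was 0.324 against 0.46 to 0.485. No explanation of this was tested.

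Among the 3497 probes without exactly 1 gene name, which no comparison of the report uses, 52 were higher and 23 lower with IL2 at a limma adjusted p under 0.05 over all probes. At an unadjusted p under 0.05 there were 313.

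Chance was tested for the 5 counts with all 35 splits of the 7 arrays into 3 and 4. For the genes higher (410), lower (178), higher at least 2-fold (222) and lower at least 2-fold (82), the real split was in each case the only 1 of 35 to reach its count, and the highest other split gave 1 gene. For the lists called by camera with its preset correlation, the real split gave 31 and was also the only 1 of 35 to reach that, but another split (IL2 replicates 1, 2 and 3 against the rest) gave 30, and the lowest gave 3. A share of 1 in 35 lies under 0.05 and is the smallest that these 35 splits can give. For the lists the margin was 1 list, so that this count hardly tells the real groups from other splits. The splits that keep the make-up of the real groups by title style number 18, too few for a share under 0.05 (at least 0.0556), and the highest other of them gave 0 genes for each gene count and 29 lists.

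The first pattern weighed was the fall of macrophage and monocyte genes. Dilution by NK cell RNA of every other cell type alike is argued against by markers whose untreated mean lay at or above the median signal. Of these, the median of 11 macrophage and monocyte markers lay below that of 13 B cell markers (-1.30 against -0.29, difference -1.004, permutation p = 0.00196 over genes). The higher of the 2 group means kept the same 11. The setting with genes at or above the median signal is a different cut and kept 10 macrophage and monocyte markers (median -1.53). Markers of a cell type may move together, so that this p does not measure the spread between arrays. Scaling between arrays is also argued against as the whole cause, with a median of at most -0.905 under the other 2 scalings. A smaller share of macrophage and monocyte RNA in the IL2 arrays, with no change within those cells, may explain the fall of the 8 bright members, of which 0% had a 95% interval wholly above -0.91, or 50% of their median fall of -1.82 (2, Hmox1 and Apoe, named after their values were seen, did not pass the test). Bright was judged by the untreated mean (the higher of the 2 group means also gave 8), and the 9 dimmer members (median -0.08), with C1qb (named after its value was seen) higher at 0.36 when adjusted over the list alone, lie outside that test. A change of expression within those cells, fewer of them surviving culture with IL2, and uneven selection between samples stay open and untested.

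The second pattern was the rise of interferon-stimulated genes. Scaling is argued against as the whole cause, since the lowest median under the other 2 scalings was 1.75. More macrophage, dendritic or B cell RNA in the IL2 arrays is argued against, since the highest of the medians of the 3 marker lists was -0.144. These medians do not address a rise of a single subset of such cells, nor induction of interferon-stimulated genes within them. A candidate explanation is interferon-gamma, whose transcript rose. It predicts a larger rise of genes preferring interferon-gamma than of genes preferring type I interferon. The difference in medians was -0.39, in the direction set down as against interferon-gamma, but it did not pass the test (permutation p = 0.117 over genes). Interferon-gamma and type I interferon thus cannot be told apart by this difference. The interferon-gamma set also does not isolate interferon. Its members Ciita (-0.08) and H2-Aa (-0.33) are also dendritic cell markers, and Socs1 (2.84) is also a STAT5 target. Ciita, H2-Aa, Ido1 (0.33) and Nos2 (0.19), named after their values were seen, were the members that did not pass the test. Of 18 genes preferring type I interferon 16 rose (median 1.89), and of 14 preferring interferon-gamma 10 rose (median 1.496), up to 4.54 for Cxcl9, while limma called 0 of 12 type I interferon ligand genes (log2 fold changes of -0.41 to 0.11).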

How the results depend on the processing

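The fits over the arrays of 1 title style were chosen after the data had been seen, and the other alternatives were planned. Genes higher and lower numbered 694 and 577 after quantile normalization again. Over the arrays whose titles give the time they numbered 81 and 22, all of them at least 2-fold (81 and 22). Over the 3 arrays whose titles do not give it, limma called 0 higher, 0 lower and 0 of either at least 2-fold, with 2630 genes at an unadjusted p under 0.05. Fewer arrays lower the power of these last fits, and the cause of the change with quantile normalization was not tested. Under the other settings with all arrays the 4 counts stayed within 1.5 times those reported. With 1 array left out, genes higher numbered 134 (without IL2 replicate 2) to 517 (without IL2 replicate 1), and genes lower 65 (without IL2 replicate 2) to 152 (without untreated replicate 3). Genes at least 2-fold higher numbered 117 to 279 and lower 51 to 77, with the lowest and highest at the same arrays. Camera called 27 to 31 lists under every setting with its preset correlation, 0 with an estimated correlation, and fry called 20. With the replicate number as a block 554 genes were higher, 351 of them among the 410, and 184 lower. Here and below this block is counted among the settings with all arrays, though IL2 replicate 1 does not enter its contrast. Its fold changes are those without IL2 replicate 1. The numbers were not taken to pair the arrays, since no label says what they stand for. Deviations from the group mean correlated at 0.460, -0.299 and 0.308 for numbers 2, 3 and 4. Untreated replicates 2 and 4 were closest to the IL2 array of the same number, and untreated replicate 3 to IL2 replicate 1 (0.454). Deviations within a group depend on one another, so that these values cannot decide whether the numbers pair the arrays.

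Of 76 named genes 66 were called, 43 of them with every 1 array left out, and 29 over the arrays whose titles give the time. Over the planned settings with all arrays, named genes gave 596 outcomes with the reported direction and side of the threshold, 4 weaker, 4 stronger and 1 reversed. With 1 array left out there were 415, 112, 1 and 4 of these. For lists they were 339, 56, 6 and 6 over settings with all arrays, and 250, 21, 6 and 10 with 1 array left out. The reversed results were uncalled, other than the cholesterol list. Cd3e (0.01) turned to -0.13 after quantile normalization again, to -0.11 over the arrays without the time, and ranged from -0.20 to 0.23 with 1 array left out. For the following lists camera's direction turned, and the median is given. Over the arrays without the time these were cholesterol (-0.00529), the BCL2 family (-0.0261), NF-kB (-0.0834), immediate early genes (-0.0734) and stromal markers (0.0912). Over the arrays with the time they were ribosomal proteins (0.0861), circadian genes (0.0110) and T cell markers (0.168). Ribosomal proteins also turned with the replicate block (0.0668) and array weights (0.0247), and ranged from -0.0569 to 0.0668 with 1 array left out. T cell markers turned with the replicate block (0.0789) and the title style as a block (0.0801), and ranged from -0.202 to 0.110. After quantile normalization again, stromal (-0.0101) and innate lymphoid (-0.0387) markers turned, and they ranged from -0.117 to 0.0316 and from -0.126 to 0.0238 with 1 array left out. The cause of these turns was not tested. Background levels per probe were not used here, so that no limit on dim genes was set.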

Other observations

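The tests of this part were planned, other than the values per title style, which were chosen after the result had been seen. Some genes of protein synthesis and folding rose. Of 18 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, all had a positive log2 fold change. Wars, the tryptophan enzyme that interferons also induce, rose by 2.40 (SE 0.21) and Rars by 0.94, with a list median of 0.60 (camera adjusted p = 4.15e-11, but adjusted p = 0.242 with an estimated correlation). Of 19 chaperonin and mitochondrial folding genes 3 rose, including Hspd1 (1.07) and Stip1 (0.85), with a median of 0.64 (camera adjusted p = 9.29e-14, but adjusted p = 0.236 with an estimated correlation). Of 22 endoplasmic reticulum folding and secretion genes 4 rose, including Sdf2l1 (0.97) and Hspa5 (0.92), the chaperone BiP, with a median of 0.59 (camera adjusted p = 4.11e-15, but adjusted p = 0.163 with an estimated correlation). Of 35 cytosolic ribosomal protein genes limma called 0, with 1 at an unadjusted p under 0.05, a median of -0.01 (camera adjusted p = 0.817) and the largest difference in Rpl12 (0.75, limma adjusted p = 0.132). Rpl12 passed the test with the replicate number as a block (limma adjusted p = 0.0419), after quantile normalization again (0.0261) and without IL2 replicate 1 (0.0376), and camera called that list lower without untreated replicate 4 (adjusted p = 0.0249) and over the arrays without the time (0.0282, where the untreated group is 1 array). Adjusted over the list alone, 12, 15, 17 and 0 genes of these 4 lists were higher. By title style, with and without the time, the medians were 0.78 and 0.30, 0.89 and 0.33, 0.70 and 0.39, and 0.09 and -0.11. Macrophage and monocyte markers had a median of -0.95 over the same arrays. The counts higher depended on the setting. After quantile normalization again they were 8, 10, 13 and 1, with the replicate number as a block 5, 9, 10 and 1, with title style as a block 3, 6, 8 and 0, among genes at or above the median signal 4, 9, 12 and 0, with array quality weights 5, 9, 12 and 0, and with centred arrays 3, 6, 10 and 0. They also depended on single arrays. For the tRNA synthetases they were 1 without untreated replicate 4 or IL2 replicate 2, 3 or 4 and 5 without IL2 replicate 1. For the chaperonins they were 1 without untreated replicate 3 or 4, 0 without IL2 replicate 2, 3 or 4, and 10 without IL2 replicate 1. For the endoplasmic reticulum they were 0 without untreated replicate 3 or 4 or IL2 replicate 2, 3 or 4, and 10 without IL2 replicate 1. Rars, Hspd1, Stip1, Sdf2l1 and Hspa5 each lost their calls without IL2 replicate 2, 3 or 4 and without 1 to 3 of the untreated arrays, at limma adjusted p-values of 0.0566 to 0.146.

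Few mitochondrial, nucleotide synthesis and proteasome genes were called. All 29 mitochondrial ribosome and import genes were positive, with C1qbp called (0.94) and a median of 0.36 (camera adjusted p = 1.37e-11, but adjusted p = 0.242 with an estimated correlation). Of 19 nucleotide synthesis genes, Nme1 (1.37, SE 0.24) and Ctps (0.94) rose, with a median of 0.53 (camera adjusted p = 1.91e-10, but adjusted p = 0.236 with an estimated correlation). Of 32 proteasome genes, Psme3, an activator subunit, rose (0.76), with a median of 0.38 (camera adjusted p = 1.04e-09, but adjusted p = 0.244 with an estimated correlation). For 39 respiratory chain genes limma called 0, with 13 at an unadjusted p under 0.05, a median of 0.27 (camera adjusted p = 2.78e-08, but adjusted p = 0.242 with an estimated correlation) and the largest difference in Ndufb6 (0.81). Adjusted over the list alone, 16, 13, 5 and 0 genes of these 4 lists were higher. Medians by title style, with and without the time, were 0.60 and 0.21, 0.74 and 0.23, 0.57 and 0.09, and 0.40 and 0.12. Over the arrays without the time the camera calls of the proteasome (adjusted p = 0.336) and respiratory chain (0.174) lists ended. Macrophage and monocyte markers had a median of -0.95 over the same arrays. C1qbp, Nme1 and Psme3 lost their calls without any 1 array other than IL2 replicate 1, at limma adjusted p-values of 0.0657 to 0.16, and Ctps without untreated replicate 4 or IL2 replicate 2 or 3 (0.0585 to 0.0751). The counts higher, in the order of the mitochondrial, nucleotide, proteasome and respiratory lists, were 6, 7, 4 and 2 after quantile normalization again, 5, 8, 2 and 1 with the replicate number as a block, and 3, 4, 1 and 2 with title style as a block. They were 4, 5, 2 and 0 among genes at or above the median signal and 3, 4, 4 and 0 with array quality weights. Without IL2 replicate 1 the counts were 4 for the mitochondrial genes, 5 for nucleotide synthesis, 3 for the proteasome (also without untreated replicate 2) and 2 for the respiratory chain.

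Of 14 p53 target genes, Ccng1, a cyclin of the DNA damage response, rose (0.63, SE 0.09), with 7 higher when adjusted over the list alone and a median of 0.58 (camera adjusted p = 2.43e-05, but adjusted p = 0.242 with an estimated correlation). The count was 5 without IL2 replicate 1 and 2 without untreated replicate 2, and 4 to 5 with either block, among genes at or above the median signal, after quantile normalization again, with centred arrays and with array quality weights. Over the same arrays macrophage and monocyte markers had a median of -0.95 and NK cell identity markers one of 1.05. Of 16 hypoxia genes, Bnip3l fell (-0.69), with 3 lower after quantile normalization again and a median of -0.09 (camera adjusted p = 0.0341, but adjusted p = 0.3 with an estimated correlation). That camera call ended without untreated replicate 2 (adjusted p = 0.534) or IL2 replicate 1 (0.0962, median -0.06), with the replicate number as a block (0.0834), with array quality weights (0.145) and over the arrays with the time (0.737). Bnip3l lost its call without 5 of the arrays (limma adjusted p-values of 0.0703 to 0.115). Camera did not call the glucocorticoid list (median -0.13, adjusted p = 0.081), in which Il7r fell, other than without IL2 replicate 4 (0.0406), after quantile normalization again (0.0293), among genes at or above the median signal (0.0363) and over the arrays without the time (0.0295, with 1 untreated array). Nor did it call the circadian list (median -0.06, mean 0.03, adjusted p = 0.628, but 0.0236 over the arrays without the time, with 1 untreated array), in which Bhlhe40 rose (1.07). Bhlhe40 lost its call without untreated replicate 3 or 4 or IL2 replicate 2, 3 or 4 (limma adjusted p-values of 0.0595 to 0.0826). Within the title styles with and without the time, the medians were 0.77 and 0.27 for p53 targets, -0.01 and -0.22 for hypoxia, -0.10 and -0.06 for glucocorticoid genes, and 0.01 and -0.06 for circadian genes.

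The T cell and G2-M scores followed the style of the sample titles more than IL2. T cell scores were -0.33, -0.38 and -0.36 in untreated replicate 2 and IL2 replicates 1 and 2, and 0.09, 0.32, 0.33 and 0.32 in untreated replicates 3 and 4 and IL2 replicates 3 and 4. In the same order, G2-M scores were -0.37, -0.42 and -0.30, and 0.18, 0.50, 0.20 and 0.21. The array quality weights were lowest for untreated replicate 2 (0.493), untreated replicate 4 (0.621) and IL2 replicate 1 (0.683).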
